A study of Homo sapiens with 2 samples.

How the data were processed

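Single-cell RNA of BJ fibroblasts 8 days after OSKM infection was measured in 2 libraries, 1 of cells that stained negative and 1 of cells that stained positive for CD13, with the Chromium Single Cell 3′ v2 chemistry per the labels' protocols. The authors deposited raw UMI counts per gene and cell in a matrix of 32643 genes and 7680 cells, with a table that names the library of each barcode. Cell Ranger 2.1.0, Seurat (no version) and the hg19 build are named in the submitters' processing notes; which steps each tool did and any filter applied to cells or genes are not given in the sources used here. All deposited counts were whole numbers, none of the gene names was repeated or blank, and the barcodes of both tables were in the same order. Gene names were used as given, and no coordinates were used because the reference at hand was of another build. The lowest UMI total of a cell was 4399 in the CD13 negative and 4313 in the CD13 positive library, and all cells were kept. At least 10% of UMIs were mitochondrially encoded in 16.6% of CD13 negative and 19.0% of CD13 positive cells. In the CD13 positive library 2 cells had under 1000 genes.

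Because each fraction had 1 library, no test was made. UMI counts were summed over the cells of each library and scaled to CPM of its total, where 1 UMI is worth 0.0145 CPM in the CD13 negative and 0.0168 CPM in the CD13 positive library. Log2 ratios were taken of CPM + 1, and fold differences of CPM itself where both libraries had more than 3 UMIs. CPM has exact Poisson, fold differences exact conditional and shares of cells exact Clopper-Pearson 95% intervals. The limit given for a count of 0 is not such an interval but 3 counts of the total. UMIs of 1 cell, and cells of 1 culture, are not independent replicates, so these intervals say nothing of variation between cultures. A gene was counted where its mean was at least 10 CPM and its ratio of CPM + 1 at least 1.5-fold. Members of lists were counted past 1.5-fold from a mean of 1 CPM. The 26 gene lists, the cell type markers and the rule for named genes were fixed before the data were examined. The rule took ANPEP, the 4 reprogramming factors, the 12 highest and 12 lowest genes by log2 ratio with a mean of at least 10 CPM (no mitochondrially encoded gene), up to 4 members per list with the largest ratio at that level, and 5 leading genes per cluster; some genes it took are not reported here. List medians used members with a mean of at least 1 CPM and were ranked among 10000 random lists of equal size matched in 20 bins of expression. Random members were drawn independently, so these ranges hold neither the shared regulation of a list's members nor variation between libraries.

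For shares of cells and list shares per cell, each cell was thinned to 5000 UMIs, the largest of 1000, 2000, 3000, 5000 and 10000 that kept at least 90% of the cells of each library. For clusters, counts were scaled to 10000 per cell and log-transformed. The 2000 genes with the highest dispersion were taken from those that differed under 1.5-fold between libraries. Then 30 principal components, 15 nearest neighbours with Jaccard weights and the Leiden method at resolution 0.5 were used (leidenalg 0.10.2, scikit-learn 1.9.0). Clusters are given by number. Doublets were sought with Scrublet in each library (scanpy 1.11.5, expected rate 5%). It called 2 CD13 negative and 15 CD13 positive cells, 0.221% of all, too few to rely on, so doublets were not removed. Whether doublets had been removed before deposit, which would also leave few calls, is not given in the sources used here. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 were used, with R 4.3.3, edgeR 4.0.16 (TMM factors) and DESeq2 1.42.0 (median-of-ratios factors) for alternative scalings.

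The procedures were tested on simulated data. Libraries of the real depths were simulated with 200 genes changed among the 7766 with at least 10 CPM over both libraries pooled, and 7738 genes reached a mean of 10 CPM in the simulated counts. Without the minimum applied again, the 1.5-fold rule called all 63 genes changed 2-fold, all 69 changed 4-fold, 32.4% of the 68 changed exactly 1.5-fold and 0 of 7566 unchanged genes. Apart from the changed genes both simulated libraries were Poisson draws from 1 profile, with no variation between cells, cultures or libraries. At these depths an unchanged gene could hardly pass, so the 0 false calls do not bear on such variation. All 7766 genes were taken at a pooled level of at least 10 CPM, so false calls were not tested for list members below it, such as LIN28A, SALL4, LEFTY1, USP44 and DNMT3B. Of 200 simulated lists without change, 12 lay outside the central 95% of random lists. Alternatives covered scaling, low-count filters, pseudocounts, the fold, the cells kept, thinning and cluster settings. Those that leave out clusters or keep only some, weight the CD13 positive library to the CD13 negative cluster mixture, leave out the 5% of cells with the highest doublet score or compare separate sets of cells, and the rule for clusters with high mesenchymal markers, were chosen after seeing the data.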

Results

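The data described BJ cells, an established human foreskin fibroblast line, 8 days after lentiviral delivery of OCT4, SOX2, KLF4 and MYC, the factors used to reprogram somatic cells to pluripotency. The cells were kept in medium with 10% fetal bovine serum until day 5 and then in embryonic stem cell medium with 20% serum replacement. At day 8 they were separated by staining for CD13, a surface aminopeptidase of fibroblasts encoded by ANPEP, and each fraction gave 1 droplet-based 3′ single-cell library. The CD13 negative library held 4063 cells and 69017538 UMIs, with a median of 16469 UMIs and 3728 genes per cell. The CD13 positive library held 3617 cells and 59466299 UMIs, with a median of 15885 UMIs and 3763 genes per cell. The median share of mitochondrially encoded UMIs was 3.81% and 4.13%. With 1 library per fraction there was no replicate check and no test was made between fractions. Every interval below is an exact 95% interval that covers counting error only. The limit given for a count of 0 is 3 counts of the total, and every count of genes is a count by size of difference between these 2 libraries.

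The first comparison asked whether the sorted antigen's own gene separated the libraries. ANPEP stood at 13.6 CPM (interval 12.7 to 14.5) in the CD13 negative library and at 88.4 CPM (86 to 90.8) in the CD13 positive library, a 6.5-fold difference (6.06 to 6.98). After every cell was thinned to 5000 UMIs, 7.06% (6.28 to 7.92) of CD13 negative and 28.2% (26.7 to 29.7) of CD13 positive cells held an ANPEP UMI. In cluster 3, described below, where the gene was low, the shares were 3.69% and 6.65%. Without thinning the shares of all cells were 15.6% and 49.1%. Among cells without a UMI of 6 mitotic genes the ANPEP difference was 4.26-fold.

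The comparison of all genes asked which transcripts differed with CD13 staining. KISS1, a secreted peptide precursor, was 13.3-fold (11.6 to 15.3) lower in CD13 negative cells, and MMP1, the interstitial collagenase, was 13-fold (11.1 to 15.3) lower. LUM, which codes for the collagen-binding proteoglycan lumican, was 11.1-fold lower. COL1A1, the main chain of type I collagen, stood at 164 CPM against 1179.5 CPM, 7.20-fold lower (7.06 to 7.35), and the metalloproteinase inhibitor TIMP3 was 8.72-fold lower. The remaining 7 of the 12 lowest genes were KLK10, PAPPA, IL1B, MGP, PTX3, LOXL2 and the mesenchymal transcription factor PRRX1, between 6.73-fold and 11.7-fold lower. These folds compare sums over each library, not a typical cell. Without thinning, KISS1, MMP1, KLK10 and MGP were detected in 1.26%, 2.29%, 1.48% and 1.58% of CD13 negative cells. In CD13 positive cells their shares were 9.95%, 9.98%, 8.18% and 9.95%. TIMP3 was more widespread, in 22.0% and 57.8% of cells, as was COL1A1, in 34.7% and 79.0%. At the other end, MT1H was 3.95-fold (3.63 to 4.30) and MT1G 3.56-fold (3.42 to 3.71) higher in CD13 negative cells. LEFTY2, a Nodal antagonist, was 3.03-fold (2.77 to 3.32) higher, and GDF3, a ligand of the same family expressed in pluripotent cells, was 2.60-fold (2.42 to 2.79) higher. MT1F, MT1X, CNFN, ANKRD1, SERPINB9, C9orf135, LINC00678 and RP11-598D14.1 completed the 12 highest, between 2.34-fold and 2.74-fold.

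Of 7775 genes with a mean of at least 10 CPM, 201 were at least 1.5-fold higher and 635 at least 1.5-fold lower in the CD13 negative library, and 33 and 241 differed by at least 2-fold. With median-of-ratios size factors the numbers were 290 higher and 493 lower, and among cells without a UMI of the mitotic genes they were 432 and 748.

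**Figure D1:**
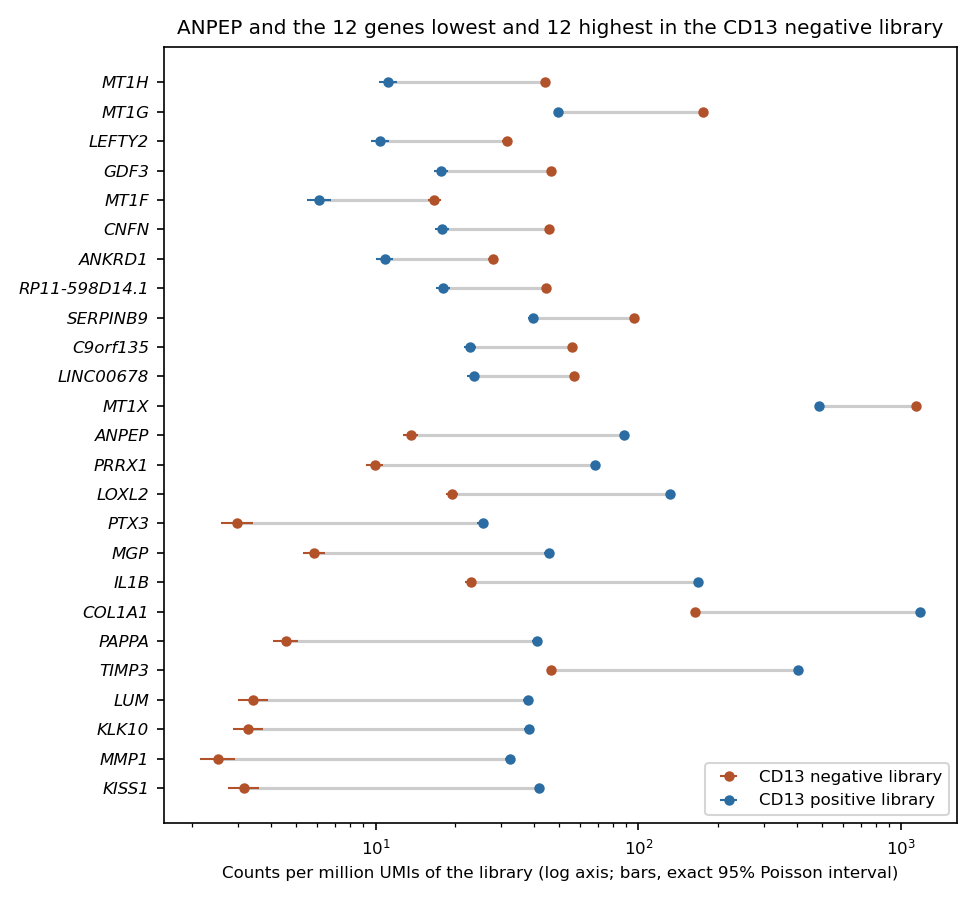
CPM (log axis) of ANPEP, the 12 genes lowest and the 12 genes highest in the CD13 negative library by log2 ratio, with exact 95% Poisson intervals, for the CD13 negative and the CD13 positive library. ANPEP stood at 13.6 and 88.4 CPM, COL1A1 at 164 and 1179.5 CPM, and MT1G at 176 and 49.4 CPM.

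The mesenchymal and matrix list was lower in CD13 negative cells, with a median log2 ratio of -1.21 over 39 measured members. In it, 27 members were at least 1.5-fold lower, none was higher by that size and 12 were in between. Besides LUM, TIMP3, COL1A1 and PRRX1, which led the list, THY1, a surface marker of fibroblasts, stood at 1153 against 1036 CPM, and TWIST1 and CDH2 also stood slightly above the CD13 positive level (these 3 were named after their values were seen). Contractile and myofibroblast genes had a median of -0.66, with 9 of 14 lower and 0 higher. Among them MYLK, the myosin light chain kinase, was 3.72-fold and TAGLN, an actin-binding protein of smooth muscle, 2.51-fold lower. Targets of YAP and TGF-beta had a median of -0.80, with 12 of 18 lower. THBS1, a matrix glycoprotein gene, was 5.87-fold lower, while ANKRD1 was the 1 member at least 1.5-fold higher. AP-1 and TEAD genes had a median of -0.73, with 9 of 15 lower, led among members with a mean of at least 10 CPM by JUNB (2.41-fold) and FOSL1 (2.05-fold). TEAD4, the 1 member higher by that size, was named after its value was seen. The medians of all 4 lists lay below all 10000 random lists matched on expression.

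Inflammatory secretory genes had a median of -1.21, with 13 of 20 lower and 0 higher. The cytokine gene IL1B stood at 23.0 CPM against 169 CPM and the chemokine genes CXCL1 and IL8 were 3.22-fold and 3.11-fold lower in CD13 negative cells. Interferon genes had a median of -0.55, with 13 of 27 lower, among them IFIT3 (2.52-fold), and IFI27 was the 1 higher member (1.68-fold). Both medians lay below all random lists. Hypoxia genes had a median of -0.36, at the 0.13 percentile. In it 5 of 14 were lower and 0 higher: P4HA2 (2.6-fold), ANGPTL4, NDRG1, BNIP3L and, named after its value was seen, CA12. With the CD13 positive library weighted to the CD13 negative mixture of clusters, described below, the hypoxia median was -0.053, inside the central 95% of random lists, and 0 of 14 members were lower. Genes of p53 and cell cycle inhibitors had a median of -0.19, at the 2.22 percentile, with 2 of 20 lower. These were CDKN1A, the cell cycle inhibitor p21, at 121 against 244 CPM, and CDKN2B, named after its value was seen.

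Pluripotency genes were higher in CD13 negative cells, with a median of 0.83 over 21 measured members. In this list 15 members were at least 1.5-fold higher and 0 lower. Among members with a mean of at least 10 CPM, LEFTY2, GDF3, the Nodal co-receptor TDGF1 (2.26-fold) and the RNA-binding protein gene L1TD1 (2.08-fold) had the largest log2 ratios. Epithelial genes had a median of 0.51, with 10 of 23 higher and 1 lower (ITGB4, named after its value was seen). SPINT2, a membrane protease inhibitor, was 2.26-fold, the junction protein gene CXADR 2.20-fold and KRT8, a keratin of simple epithelia, 1.90-fold higher. Metallothionein genes, which code for metal-binding proteins, had a median of 1.13, with 6 of 8 members higher and 0 lower. MT2A, named after its value was seen, stood at 1356 against 1444 CPM. The medians of these 3 lists lay above all random lists. The viral factors could not be told from the cells' own genes by 3′ counts: POU5F1 stood at 17.1 against 14.6 CPM, SOX2 at 7.82 against 5.55 CPM, KLF4 at 4.97 against 3.92 CPM and MYC at 36.0 against 51.2 CPM. POU5F1 and SOX2 also belonged to the pluripotency list.

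Cell cycle lists were slightly higher in CD13 negative cells. S phase genes had a median of 0.29 over 41 members, and G2 and M phase genes a median of 0.22, with 3 of 54 higher (CDK1, HMGB2 and UBE2C) and FAM64A 2.06-fold lower. Both medians lay above all random lists. Nuclear-encoded oxidative phosphorylation genes had a median of 0.20 (99.9 percentile), with 0 of 36 members past 1.5-fold. Chromatin regulators had a median of 0.12 (99.7 percentile), and 2 of 29 passed 1.5-fold: TET1, which oxidises methylated cytosine (1.79-fold), and the DNA methyltransferase gene DNMT3B (2.13-fold), the latter named after its value was seen. Both also belonged to the pluripotency list and were already counted among its higher members. With the same weighting the chromatin median was 0.022, inside the central 95% of random lists, and 0 of 29 members passed 1.5-fold. Histone genes had a median of 0.16 over 13 members, at the upper edge of the central 95% of random lists, and HIST1H4C alone passed 1.5-fold (1.54-fold).

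Keratinocyte genes had a median of -0.62 over 7 members, at the 0.37 percentile. Lower were KRT14 (3.61-fold), KRT6A (2.99-fold) and, named after their values were seen, KRT16, DSG3 and KRT13, and SFN was 1.6-fold higher. In cluster 8, described below, the keratinocyte median went the other way, at 0.86 with 5 of 7 members higher and 0 lower in 41 CD13 negative against 226 CD13 positive cells. Surface markers used in reprogramming sorts went both ways, with 5 of 19 higher, 6 lower and a median of 0.16 (99.1 percentile). ANPEP, whose product was sorted on, was 1 of the 6 lower, which is no finding apart from the sort. CD44, ENG and ALCAM were 2.17-fold, 2.51-fold and 2.1-fold lower in CD13 negative cells, and the 5 higher, named after their values were seen except for F11R, were EPCAM, PODXL, F11R, CDH1 and PROM1. CD44 and ENG were also in the mesenchymal list, EPCAM, F11R and CDH1 in the epithelial list and PODXL in the pluripotency list. The medians of glycolysis (-0.02), cholesterol synthesis (-0.05), heat shock and unfolded protein (0.04), neural (-0.05), trophoblast and amnion (-0.13) and endothelial and blood genes (0.02) lay inside the central 95% of random lists. In the glycolysis list the lactate transporter gene SLC16A3 was 2.0-fold lower. Of the mesendoderm list only 2 of 14 genes reached 1 CPM, HHEX and MESP1, with log2 ratios of -0.51 and -0.21. The 4 reprogramming factor genes had a median of 0.24, also inside that range.

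**Figure D2:**
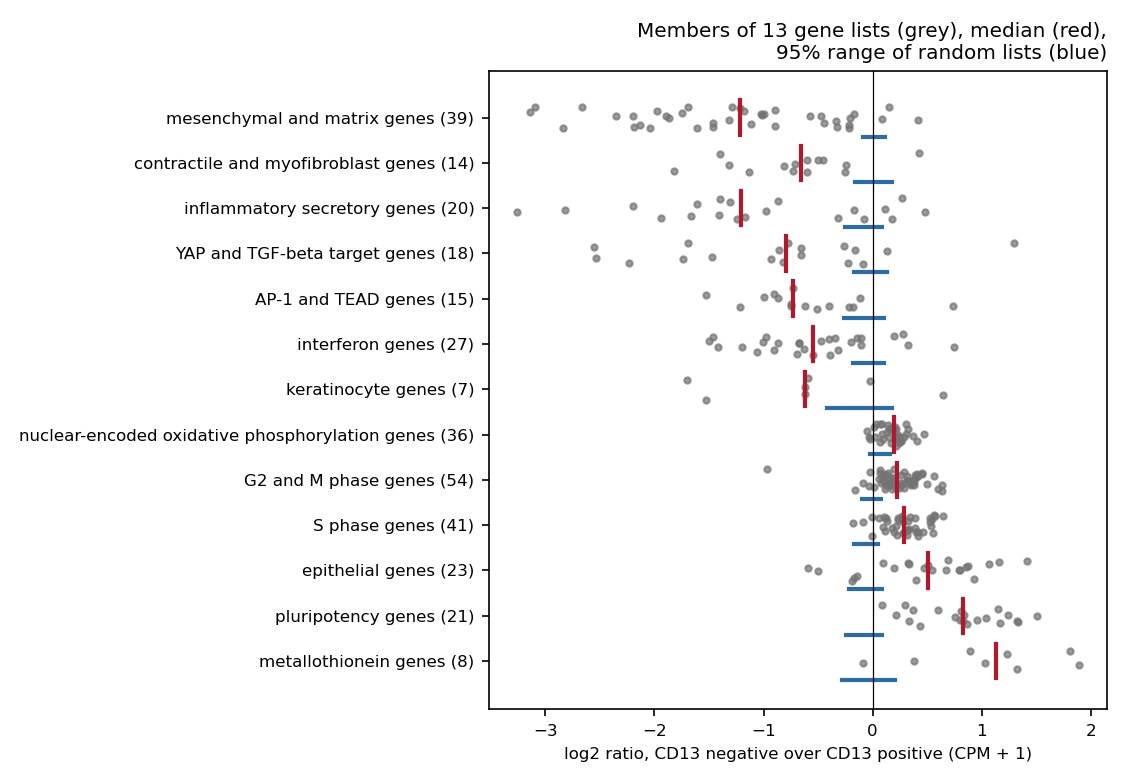
Log2 ratio of CD13 negative over CD13 positive for each measured member of 13 gene lists (grey points, number of members in parentheses), with the list median (red) and the central 95% of medians of random lists matched on expression (blue). Medians ran from -1.21 for mesenchymal and matrix genes to 1.13 for metallothionein genes.

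Single cells were compared at 5000 UMIs, which left out 213 CD13 negative and 248 CD13 positive cells. Mesenchymal and matrix genes took a median of 1.68% of a CD13 negative cell's UMIs (10th to 90th percentile 1.04 to 2.82) and 2.74% of a CD13 positive cell's (1.40 to 5.36). Epithelial genes took 0.380% and 0.140%, S phase genes 0.180% and 0.120%, and G2 and M phase genes 0.420% and 0.260%. Without thinning these medians were 1.69% and 2.73%, 0.369% and 0.148%, 0.180% and 0.124%, and 0.427% and 0.268%. COL1A1 was detected in 21.6% (20.3 to 22.9) of CD13 negative and 64.8% (63.2 to 66.4) of CD13 positive cells. In cluster 4, where this gene was low, the shares were 6.95% and 20.1% at the same depth. NANOG, a core pluripotency factor, was detected in 6.83% (6.05 to 7.67) and 3.95% (3.32 to 4.66) of cells. In the matrix-rich cluster 5 it was detected in 0 of 162 CD13 negative cells, which allows a share of up to 1.85%, and in 0.141% of CD13 positive cells. Inside the clusters that held most cells with a NANOG UMI the shares were 5.77% (4.48 to 7.29) and 3.02% (1.70 to 4.94) in cluster 1, 10.6% and 10.8% in cluster 2, 6.76% and 8.17% in cluster 3, and 7.43% and 6.23% in cluster 4, with overlapping intervals in each. EPCAM was detected in 3.66% and 1.84%, CDH1 in 1.25% and 0.712%, LIN28A in 1.12% and 0.208%, and DPPA4 in 0.364% and 0.178%. In cluster 5 of the CD13 positive library EPCAM and DPPA4 were each detected in 0.141% of cells, and CDH1 and LIN28A in 0 of 711 cells, which allows up to 0.422%. In cluster 5 of the CD13 negative library each of the 4 genes was detected in 0 of 162 cells. The CD13 negative shares of CDH1, LIN28A and DPPA4 lay under the limit of 1.85%, which is wide because cluster 5 gave 162 cells. The CDH1 share lay above the 0.359% that 0 of 835 CD13 negative cells of cluster 4 allows. The LIN28A share lay above the 0.422% of cluster 5 of the CD13 positive library. In CD13 negative cells of cluster 4 LIN28A was detected in 0.479% (0.131 to 1.22). The DPPA4 share lay under 1.85% and could not be told from background by that limit. Its intervals, 0.199% to 0.609% in the CD13 negative and 0.0654% to 0.387% in the CD13 positive library, overlapped. No difference was therefore resolved at this depth. In clusters 1, 2, 3 and 4 EPCAM was detected in 2.66% and 1.01%, 7.07% and 6.22%, 4.05% and 2.09%, and 2.99% and 3.4% of cells. CDH1 was detected in 1.24% and 0.806% of cells of cluster 1, 2.83% and 3.35% of cluster 2 and 1.6% and 0.760% of cluster 3, and in 0 of 835 and 0 of 353 cells of cluster 4, which allows up to 0.359% and 0.850%. THY1 was detected in 95.1% and 93.0% of cells. MKI67, a proliferation marker, was detected in 36.3% and 31.5% of cells, against 2.44% and 4.04% in cluster 8, and its shares in clusters 1, 2, 3 and 4 were 51.2% and 58.5%, 54.3% and 51%, 8.85% and 6.46%, and 31.6% and 27.2%. Without thinning, COL1A1 was detected in 34.7% and 79.0%, NANOG in 15.9% and 10.1%, EPCAM in 9.62% and 5.34%, CDH1 in 3.08% and 1.24%, and LIN28A in 3.27% (2.75 to 3.87) and 0.581% of cells. NANOG shares in clusters 1 to 4 were then 17.9% and 16.4%, 15.4% and 15.1%, 19.7% and 19.9%, and 16.0% and 16.3%. The unthinned CD13 negative shares of CDH1 and LIN28A lay above the 1.84% that 0 of 163 CD13 negative cells of cluster 5 allows. The unthinned shares were 0.886% and 0.470% for DPPA4, 99% and 98.6% for THY1, and 57.6% and 46.7% for MKI67. The DPPA4 share stayed under that limit, which rests on 163 cells and cannot decide whether the libraries differed. Unthinned median depths were 13180 and 15736 UMIs in cluster 5, 19088 and 20698 in cluster 4, and 21827 and 21180 in cluster 8.

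**Figure D3:**
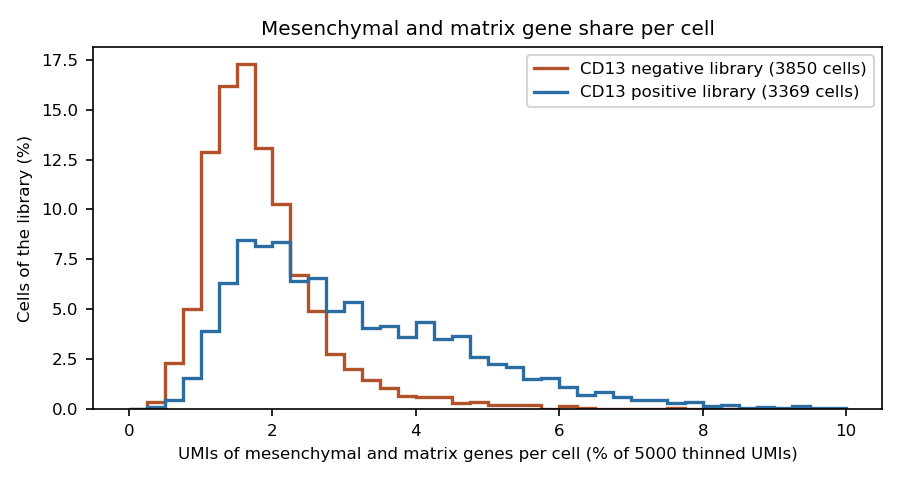
Percent of each library's cells (vertical axis) by the share of 5000 thinned UMIs in mesenchymal and matrix genes (horizontal axis, bins of 0.25%). The CD13 negative library (3850 cells) had a median of 1.68% and the CD13 positive library (3369 cells) a median of 2.74% with a long upper tail.

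Cells of both libraries were clustered together without the genes that differed at least 1.5-fold between libraries, to ask whether the fractions held different mixtures of cells. There were 9 clusters. Cluster 5, whose 10 matrix markers at least 2-fold above the remaining cells included COL1A1, FN1 and SPARC, held 4.01% (3.43 to 4.66) of CD13 negative and 20.1% (18.8 to 21.5) of CD13 positive cells; its leading genes were PAPPA, CXCL10, COL5A3, TMEM132B and CYP26B1. Cluster 6, led by MMP1, ESM1, FGF5, KISS1 and G0S2, held 1.72% and 11.6%, and cluster 7, led by IL8, MMP3, PTX3, EFEMP1 and KIAA1199, held 1.45% and 7.24%. Cluster 8, led by LYNX1, SLURP1, SPRR3, KRT14 and SPRR1A, several of them genes of stratified epithelium, held 1.01% and 6.25%. Conversely, cluster 1, led by HIST1H4C, HIST1H1B, CENPA, HIST1H1A and RP11-554I8.2, held 27.8% (26.4 to 29.2) and 13.8% (12.7 to 15). Cluster 4, led by LINC00437, LINC01048, IL31RA, RP11-865I6.2 and ZBTB20-AS1, held 21.5% and 10.3%. Cluster 3, with PGAM2, TAGLN3, HOXD1 and RGS5 among its leading genes, held 20.2% and 14.7%. Cluster 2, with CEACAM1, COL17A1, ADAMTS15 and SUSD2 among its leading genes, held 21.0% and 14.8%, and cluster 9 (led by RP11-180C1.1, LINC01133, SLURP1, PIFO and KRT6A) 1.23% and 1.08%.

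Clusters 5, 6 and 7 together held 7.19% (6.41 to 8.02) of CD13 negative and 39.0% (37.4 to 40.6) of CD13 positive cells, and clusters 1, 3 and 4 held 69.5% (68.1 to 70.9) and 38.9% (37.3 to 40.5). The CD13 sort sets which cells enter each library, and a cluster mostly of 1 library cannot be told from that library. Clusters 2, 7 and 9 had medians of 6762.5, 6112 and 6414 UMIs per cell. Their mitochondrially encoded shares were 11.6%, 10.5% and 0.0515%, against 3.28% in cluster 1, and together they held 23.7% of CD13 negative and 23.1% of CD13 positive cells.

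**Figure D4:**
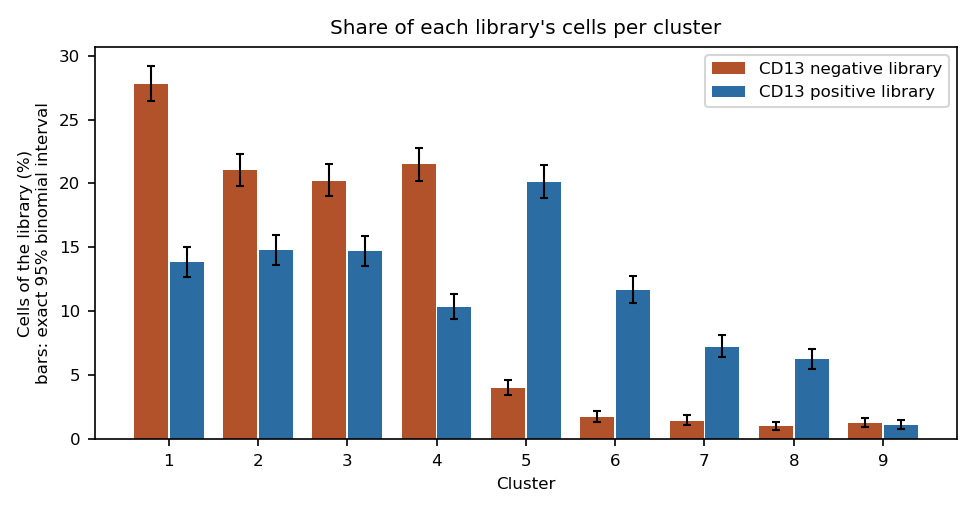
Percent of each library's cells in clusters 1 to 9, with exact 95% binomial intervals. Clusters 1 to 4 held 90.6% of CD13 negative and 53.7% of CD13 positive cells, and cluster 5 held 4.01% and 20.1%.

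Over clusters 1, 3 and 4 (2825 CD13 negative cells with 56043233 UMIs), 18 genes were at least 1.5-fold higher and 119 lower in CD13 negative cells. ANPEP was 2.92-fold (2.56 to 3.32) lower there, COL1A1 4.07-fold (3.88 to 4.28) and TIMP3 4.90-fold (4.57 to 5.25) lower, and LEFTY2 2.69-fold (2.37 to 3.06) higher. The list medians were -0.58 for mesenchymal and matrix, 0.38 for pluripotency, 0.61 for metallothionein and 0.095 for epithelial genes, and -1.15 for keratinocyte genes (5 of 7 lower). KRT14, a member of the keratinocyte list, stood at 246 CPM in cluster 8 and at 2.68 CPM over all other cells. Whether free RNA or doublets from cluster 8 gave the keratinocyte difference in clusters 1, 3 and 4 was not tested. Over clusters 5, 6 and 7 (292 CD13 negative cells with 3926788 UMIs), 155 genes were at least 1.5-fold higher and 148 lower in CD13 negative cells. Fewer UMIs leave more counting error in the counts of genes over clusters 5, 6 and 7. There ANPEP was 2.15-fold (1.93 to 2.41) and COL1A1 1.53-fold (1.5 to 1.57) lower, and the mesenchymal and matrix median was -0.24. Inflammatory secretory genes had a median of 0.46 in these clusters, with 10 of 20 higher and 3 lower, the opposite direction to the whole libraries. Only cluster 6 showed this clearly, with a median of 0.95, 12 higher and 4 lower. The medians were -0.048 in cluster 5 (3 higher, 6 lower) and -0.0040 in cluster 7 (2 higher, 5 lower). Of the other lists whose median in the whole libraries had a 95% interval over members without 0, 4 also had the opposite sign over clusters 5, 6 and 7. These were interferon (0.098), S phase (-0.11), G2 and M phase (-0.11) and chromatin regulator genes (-0.027). Of the lists whose interval held 0, so did histone (-0.13), neural (0.11), heat shock and unfolded protein (-0.062), p53 and cell cycle inhibitor genes (0.0032) and surface markers (-0.030, or 0.015 over members with at least 1 CPM there). The mesendoderm median of 0.31 rested on 2 genes.

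The libraries were also compared with the CD13 positive library weighted to the CD13 negative library's share of cells in each cluster, an alternative chosen after seeing the data. ANPEP was then 2.7-fold lower in CD13 negative cells, and 22 genes were at least 1.5-fold higher and 126 lower. Mesenchymal and matrix genes had a median of -0.51 (16 of 39 lower), interferon genes -0.37 (7 of 27 lower), AP-1 and TEAD genes -0.22 (1 of 15 lower), and targets of YAP and TGF-beta -0.20 (4 of 18 lower, 1 higher). Inflammatory secretory genes had a median of -0.18 (5 of 20 lower, 1 higher), contractile genes -0.10 (1 of 14 lower), genes of p53 and cell cycle inhibitors -0.19 (0 of 20 lower) and keratinocyte genes -0.46 (3 of 7 lower). Pluripotency genes had a median of 0.35 (6 of 21 higher), epithelial genes 0.22 (3 of 23 higher), metallothionein genes 0.66 (5 of 8 higher), S phase genes 0.054, G2 and M phase genes 0.079 and oxidative phosphorylation genes 0.089. Each of these medians lay outside the central 95% of random lists. So did those of surface markers (0.060, 1 of 19 higher and 2 lower), histone genes (0.11) and endothelial and blood genes, the last at -0.33 against 0.02 without weighting. The random range covers the draw of genes only, not variation between libraries or shared regulation within a list. For S phase genes it ran from -0.095 to 0.0091, so even a small median lay outside it.

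The last comparison set the difference between libraries against the difference, within a library, between cells without and with an ANPEP UMI. Among 3617 CD13 positive cells, 1842 had no ANPEP UMI and 1775 had at least 1. The mesenchymal and matrix median of cells without over cells with a UMI was -1.0, the epithelial median 0.82, the pluripotency median 0.76 and the metallothionein median 0.98. Among 4063 CD13 negative cells, 3428 without and 635 with a UMI gave medians of -1.0, 0.22, 0.32 and 0.79. Across 7774 genes, which are not independent replicates, the within-library log2 ratios correlated with those between libraries at Pearson r = 0.904 and Spearman rho = 0.866 in the CD13 positive library. In the CD13 negative library r was 0.866 and rho 0.795. With both ratios taken from separate random sets of cells, so that no cell entered both, r was 0.843 in the CD13 positive and 0.813 in the CD13 negative library. A cell without an ANPEP UMI may still express the gene, since the count depends on depth. With thinned cells r was 0.792 and 0.679, and the epithelial median of the CD13 negative library was 0.045. The split also divided clusters. Without thinning, 72.7%, 82.9%, 69.5% and 66.4% of CD13 positive cells of clusters 5, 6, 7 and 8 held an ANPEP UMI. In clusters 1, 2, 3 and 4 the shares were 30.2%, 36.4%, 21.8% and 26.2%. These correlations were not computed inside clusters, so they do not separate CD13 from cluster mixture.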

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

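Alternatives by cluster, cluster mixture, doublet score and separate sets of cells were chosen after seeing the data. Among list medians whose 95% interval over members excluded 0, 5 changed direction in clusters 5, 6 and 7 alone: inflammatory secretory 0.46, interferon 0.073, S phase -0.11, G2 and M phase -0.11 and chromatin regulator genes -0.027. Under the other alternatives counted here no such median did, and neither the ANPEP fold nor the correlations did under any. Of 558 values under alternatives, 455 stayed within 1.5 times a count, the interval of a value or 0.05 of a correlation, 98 moved further and 5 turned. A list median could count as turned only where its interval over members excluded 0. Sign changes of other lists are among the values that stayed or moved, and a wide interval makes staying easy. Where no cause is named, the cause was not tested. Genes at least 1.5-fold higher and lower in CD13 negative cells (201 and 635) numbered 442 and 1357 from a mean of 1 CPM, 468 and 1489 with no filter, 68 and 172 from 50 CPM, 113 and 401 with a pseudocount of 10, and 33 and 241 at 2-fold, as these settings admit more or fewer genes or shrink low ratios. They numbered 18 and 119 in clusters 1, 3 and 4 alone, 155 and 148 in clusters 5, 6 and 7 alone, 22 and 126 with the CD13 positive library weighted to the CD13 negative cluster mixture, and 432 were higher among cells without a UMI of the mitotic genes. The counts in clusters 5, 6 and 7 rest on 292 CD13 negative cells and hold more counting error. Other scalings gave 265 and 525 (TMM), 290 and 493 (median of ratios) and 295 and 704 (totals without mitochondrially encoded and ribosomal protein genes), and 213 and 685 were counted without clusters 2, 7 and 9. The ANPEP difference (6.5-fold) was 6.05-fold as the mean of each cell's CPM, 5.86-fold over thinned cells, 4.26-fold without cells holding mitotic UMIs, 7.23-fold without clusters 2, 7 and 9, 2.92-fold in clusters 1, 3 and 4, 2.15-fold in clusters 5, 6 and 7 and 2.7-fold with the weighted mixture, which also gave medians of -0.51 for mesenchymal and matrix and 0.35 for pluripotency genes. In clusters 5, 6 and 7, over members with at least 1 CPM there, the medians were -0.24 for mesenchymal and matrix, 0.38 for pluripotency and 0.45 for epithelial genes; over the members measured in the whole libraries interferon was 0.098 and epithelial 0.042. In clusters 1, 3 and 4 the medians were -0.58 for mesenchymal and matrix, 0.095 for epithelial and 0.38 for pluripotency genes, and with a pseudocount of 10 the pluripotency median was 0.38, since most of its members are low. Clusters with mesenchymal markers 2-fold or more above the remaining cells, a rule set after seeing them, held 7.19% and 39.0% of the libraries' cells, 4.53% and 32.6% at resolution 1.0, and 5.73% and 30.6% with no gene left out. Across genes, r within the CD13 negative library was 0.679 and within the CD13 positive library 0.792 with thinned cells, and 0.813 and 0.843 with separate sets of cells. Leaving out the 17 called doublets moved too few cells to test anything. Its values are nevertheless among the 558 and were nearly bound to stay, so the tally overstates stability. Depth limits genes such as LIN28A and DPPA4, detected in under 2% of thinned cells.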

Other observations

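The tests of shallower cells, of damaged cells and of handling were written down before their results were seen, and the remaining tests after. Both free RNA tests were also revised once their values were known: for matrix genes the whole interval, and no longer the median alone, had to lie within the bounds, and for metallothionein genes the clusters pooled, the depth correction and the counting bound were changed, and a version on the members past 1.5-fold was tried.

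Inflammatory secretory genes, lower in CD13 negative cells over the whole libraries, had median log2 ratios of CD13 negative over CD13 positive of -0.67, -0.61, -0.46 and -0.12 in clusters 1, 2, 3 and 4 and -0.49 in cluster 8. The medians lay within 0.05 of 0 in clusters 5, 7 and 9. Cluster 6 alone went clearly the other way, with a median of 0.95 and 12 of 20 members at least 1.5-fold higher in its 70 CD13 negative cells and 4 lower. Cluster 9, with 89 cells, had almost no mitochondrially encoded UMIs (0.0515%), and MALAT1, a nuclear RNA, stood at 206 CPM there against 8882 CPM in cluster 1. Its endoplasmic reticulum and membrane protein genes had a median log2 ratio to clusters 1, 3 and 4 of -0.96 and its cytosolic protein genes one of 0.43.

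The lower level of mesenchymal and matrix genes may in part reflect the mixture of clusters. With the CD13 positive library weighted to the CD13 negative cluster mixture, the list median moved from -1.21 to -0.51, which still lay below the 95% range of random lists, which argues against this mixture as the whole difference; mixtures within clusters stay open. Doublets with cells of clusters 5 and 6 would be deep, but in the shallower cells of clusters 1, 3 and 4 the median was -0.48 against -0.58 in all their cells. Cells of cluster 7 had a median of 6112 UMIs, so doublets with them could stay among the shallower cells and are left open. Free RNA in the CD13 positive suspension stays open: it would give equal UMIs per cell in clusters 1 and 4, and the median ratio over 25 members was 1.49, just inside the limit of 1.5 set for it, with an interval over members of 1.21 to 2.30 that crosses it and members from 0.307 (COL3A1) to 11.2 (TIMP3). A difference that goes with CD13 itself also stays open.

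Clusters 2 and 7, with few UMIs per cell, are consistent with damaged cells that had lost cytosolic RNA. Genes of endoplasmic reticulum and membrane proteins, whose transcripts are held at membranes, exceeded cytosolic protein genes by 1.48 in median log2 ratio in cluster 2 (against clusters 1, 3 and 4) and by 1.58 in cluster 7 (against clusters 5 and 6), over 40 genes of each kind. Less deep sampling of the same cells would leave the mitochondrially encoded share alike, but it was 3.34 times higher in cluster 2. Across 7762 genes the ratios of cluster 2 and cluster 7 correlated at r = 0.747. No biological explanation was tested, and a cell state with high secretory output stays open.

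Metallothionein genes were higher in CD13 negative cells, and a candidate explanation is that their expression goes with low CD13; weighting to the CD13 negative cluster mixture left a median of 0.66, above the range of random lists. Free RNA would add alike UMIs per cell in each cluster, but over all 8 members the excess at equal depth was 2.33 UMIs per cell in clusters 5, 6 and 8 and 26.7 in cluster 1, a ratio of 0.0874 (counting error allows up to 0.126), and 0.0763 over the 6 members past 1.5-fold. By cluster the ratio to cluster 1 was 0.0754 in cluster 5, 0.299 in cluster 6 (up to 0.385) and 0.0271 in cluster 8, each under the limit of 0.5 set for it, but 0.721 in cluster 3 and 0.828 in cluster 9. Handling that differed between libraries would not separate cells inside a library, yet in clusters 1, 3 and 4 the list median of cells without over cells with an ANPEP UMI was 0.68 in the CD13 negative and 0.42 in the CD13 positive library, above the ranges of random lists. This is a hypothesis found and tested on the same cells, and handling may still add to the difference.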
